A study of Danio rerio with 2 samples.

How the data were processed

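ATAC-seq libraries were made from single zebrafish embryos at the 1-somite stage, per the labels' protocols, after removal of chorion and yolk, with a 1 µl aliquot kept for genotyping. There was 1 wild type and 1 npas4l mutant library, assigned to genotype by the genotype given in the labels, and no other library was used. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, Picard 2.9.0, MACS2, deepTools 2.5.4, DESeq2 1.14.1 and DESeq, and the builds GRCz10 and danRer10, without giving the role of each. How regions of both libraries were merged, whether duplicates were removed and whether read ends were shifted for the transposase is not given in the sources used here.

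The deposited table has 35854 regions that do not overlap, with a median width of 389 bp (180 to 39743 bp). Its library columns hold whole-number scores that are normalised read counts rounded by the authors, as the values show. Mutant values fall on whole reads times 1.06505 for 99.96% of values up to 4000 (93.9% by chance, where a value matches if a whole read rounds to it), 9 whole numbers from 20 to 159 never occur among 23221 mutant regions, and the corresponding numbers are 1.98 times as frequent in the wild type. The wild type factor is its reciprocal, 0.939. Reads were recovered by dividing by these factors and rounding, giving 7853828 wild type and 7066666 mutant reads in regions. These factors are estimates from the values, and the recovered reads were used only for counting intervals, floors and random draws. The deposited log2 ratio equals log2 of mutant + 1 over wild type + 1, per the file headers for its direction and per its values for the formula. The deposited fraction of a region that overlaps the gene body, per the file headers, was used to say whether a region lies inside its gene. Regions were assigned to genes as in the deposited table, with 17484 regions (48.8%) assigned to 14589 genes. The table gave a symbol for 14932 of these, a gene name table gave one for 2010 more, and 542 had none; 16446 assigned regions had their identifier in that name table. Coordinates are those of the deposited table on GRCz10, and whether its starts count from 0 or 1 is not given in the sources used here.

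The measure was the log2 ratio of mutant over wild type with a pseudocount of 1, which understates differences of low regions, and folds are on the same scale. Values were used as the authors scaled them. The minimum of 20 on the mean of both libraries removed 0 regions, since the lowest mean was 20.5. With 1 library per genotype no test of genotype was made. Regions were counted by a rule of size of at least 2-fold. The 95% interval of a region is the exact Clopper-Pearson interval of the split of its recovered reads, and it covers counting error only. A floor of 3 reads per library was used where a library had 0. Counting error alone was simulated by 100 binomial draws. The regions of a gene list were summarised by the median with its order-statistic 95% interval and by the percentile of that median among 10000 random lists of assigned regions of the same size matched on level deciles, as a description of these libraries. Percentiles with 1 region per gene were matched on promoter class as well as level. Those with regions up to 50 kb away added were matched likewise, and their random lists also drew on unassigned regions within that distance of a TSS. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

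Before the data were examined, the genotype groups, the measure, the rule of size, the alternatives and 15 gene lists were fixed: endothelial, hematopoietic and erythroid, myeloid, cardiac mesoderm, pronephric mesoderm, paraxial mesoderm and somite, notochord and prechordal plate, neural, neural crest and placode, epidermis, endoderm, hatching gland, yolk syncytial layer, broadly expressed control, and known targets of Npas4l. Together 254 regions fell in at least 1 list and 9 in more than 1, the known targets not counted. The rule for named regions, fixed at the same point, took all regions of npas4l, the region with the highest mean and the one with the largest absolute log2 ratio of 13 regulators of blood, vascular and cardiac fate, the 12 lowest and 12 highest regions with a gene symbol other than a clone name, as matched by common clone prefixes (at most 1 per gene), and up to 4 regions with the largest absolute log2 ratio per list. Other regions of the same 13 genes were added after their values were seen, as were regions without an assigned gene given to the nearest TSS of the table within 50 kb and the gene families of the closing observations. The match on promoter class, 1 region per gene and leaving out regions near absent in 1 library were also chosen after the data were seen.

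The procedure was tested on simulated data drawn from these libraries' means. The 2-fold rule recovered 52% of 50 regions made 2-fold higher and 40% of 50 made 2-fold lower, 98% and 100% of those changed 4-fold, and called 0.204% of 35654 unchanged regions of the 35854. For the percentiles, over the 17484 assigned regions, 3 of 100 random lists without a shift lay under 2.5 or over 97.5, and 100 of 100 with a shift of −0.3 lay under 2.5. The simulated data held counting error only, which was less than the spread between these libraries, so these rates do not carry over to them. The lists without a shift were random draws from the same regions, so their rate only checks the calculation. Motif enrichment and assignment by a genome annotation were not done.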

Results

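Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in whole zebrafish embryos at the 1-somite stage. One library came from a wild type embryo and 1 from an embryo homozygous for the npas4l allele bns297. Npas4l is the bHLH-PAS transcription factor mutated in cloche embryos and stands at the top of endothelial and blood cell specification. The deposited table held 35854 regions on GRCz10, of which 13036 lay within 1 kb of the transcription start site (TSS) of their assigned gene, 4448 had an assigned gene beyond 1 kb and 18370 had no assigned gene. The regions held 7853828 recovered reads in the wild type library and 7066666 in the mutant library, and the median normalised read count per region was 94 in both. There was 1 library per genotype, so no difference between genotypes was tested and no p-value is given. Each log2 ratio is mutant over wild type and carries a 95% interval in parentheses. For a single region that interval is exact (Clopper-Pearson) and covers counting error only, since PCR reads without molecular identifiers are not independent molecules, and for a group of regions it is that of the median over its regions. The genotype of each library rests on its label. Unless said otherwise, a value beside a gene name is that of 1 region, and other regions of the gene may differ in direction. The genes npas4l, spi1b and sox7 were not analysed here.

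The comparison asked which regions differed in accessibility between an embryo without Npas4l function and a wild type embryo at the onset of somite formation, beginning with genes that direct endothelial and blood cell fate. All 3 regions assigned to etv2 (ENSDARG00000053868), an ETS factor that drives endothelial specification, were lower in the mutant library, by 1.28-fold to 1.48-fold. At lmo2 (ENSDARG00000095019), a cofactor of the blood and vascular factor Tal1, the upstream region was 3.06-fold lower and an intragenic region 1.76-fold lower, while its promoter differed by less than counting error. The promoter of kdrl (ENSDARG00000105215), a VEGF receptor of endothelial cells, was 2.79-fold lower, and a region at tek (ENSDARG00000028663), the angiopoietin receptor, was 2.696-fold lower. The region with the largest difference in the blood list, at znfl2a (ENSDARG00000008333), was 3.76-fold lower.

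The etv2 regions lay on chromosome 16. The promoter region, 42063813 to 42064030, held 600 normalised reads in the mutant and 770 in the wild type library, a log2 ratio of −0.36 (−0.52 to −0.20). Inside the gene body, the region at 42061629 to 42061820 held 550 against 736, a log2 ratio of −0.42 (−0.58 to −0.26), and the region at 42059124 to 42059421 held 285 against 421, a log2 ratio of −0.56 (−0.78 to −0.34). On chromosome 18, the upstream lmo2 region at 38303882 to 38304130 lay 3863 bp from the TSS, outside the gene body, and held 16 against 51 normalised reads, a log2 ratio of −1.61 (−2.60 to −0.82). The intragenic lmo2 region at 38309461 to 38309847 had a log2 ratio of −0.81 (−1.34 to −0.31), and the lmo2 promoter at 38307779 to 38308180 had −0.17 (−0.60 to 0.24). A region without an assigned gene, 15.0 kb from the lmo2 TSS at 38322721 to 38323031, went the other way, with 53 normalised reads in the mutant and 8 in the wild type library (2.58, 1.62 to 3.87). It was chosen after its value was seen.

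The kdrl promoter on chromosome 14, 32704372 to 32704712, held 18 against 52 normalised reads, a log2 ratio of −1.48 (−2.39 to −0.71), which lay at the 2.33 percentile of the regions in its level decile. The tek region on chromosome 5, 470151 to 470516, lay outside the gene body and held 22 against 61, a log2 ratio of −1.43 (−2.23 to −0.72). The znfl2a region on chromosome 2, 134525 to 134822, held 36 against 138, a log2 ratio of −1.91 (−2.51 to −1.38), and lay at the 0.349 percentile of its level decile. For gata1a (ENSDARG00000013477), the erythroid GATA factor, 15 against 29 normalised reads gave a log2 ratio of −0.91 (−1.99 to −0.01), at the 17.6 percentile of its level decile.

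Other early regulators of these lineages went in both directions. The region assigned to tal1 (ENSDARG00000019930), a bHLH factor of blood and endothelial progenitors, had a log2 ratio of −0.26 (−0.53 to 0.01). Of 5 further regions whose nearest TSS was that of tal1, the ones 16.9 kb and 10.9 kb away had −0.37 (−0.65 to −0.11) and −0.28 (−0.41 to −0.14), and the one 5.61 kb away had 0.46 (0.08 to 0.83). The 3 regions inside gata2a (ENSDARG00000059327), a GATA factor of the same progenitors, had log2 ratios of −0.29 (−0.57 to −0.02), −0.18 (−0.55 to 0.19) and −0.13 (−0.47 to 0.20). The ETS gene fli1a (ENSDARG00000054632) did not share the direction of etv2, with 0.22 (0.02 to 0.42) at its region outside the gene body and −0.17 (−0.45 to 0.11) inside it. The promoter of tspan18b (ENSDARG00000015015), a tetraspanin gene, had 0.10 (−0.22 to 0.41), and that of sox18 (ENSDARG00000058598), an endothelial SoxF factor, −0.43 (−1.01 to 0.13). At hand2 (ENSDARG00000008305), a factor of lateral plate and cardiac mesoderm, the promoter had −0.37 (−0.72 to −0.02) and a region outside the gene body −0.88 (−1.60 to −0.26). Regions without an assigned gene were looked at around these genes after their values were seen. Of 4 nearest to hand2, 3 lay below 0, the one 47.0 kb away being 2.33-fold lower in the mutant library, and the one 24.4 kb away had 0.13 (−0.32 to 0.58). The region 9.22 kb from sox18 had −0.61 (−1.03 to −0.20), and those 27.9 kb and 24.5 kb from fli1a had 0.44 (0.002 to 0.90) and 0.55 (−0.01 to 1.139). The promoter of the cardiac gene nkx2.5 (ENSDARG00000018004) had −0.42 (−1.05 to 0.23).

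**Figure D1:**
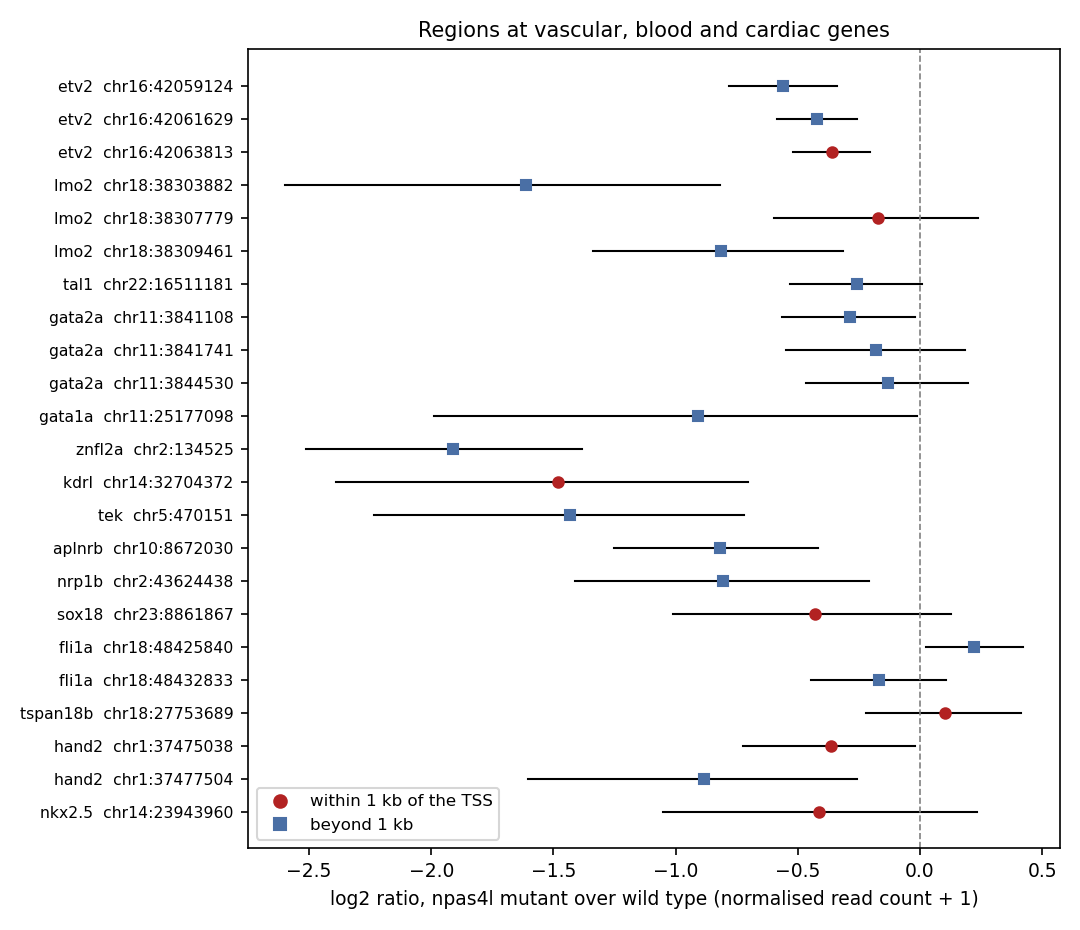
Log2 ratio of the normalised read count + 1, npas4l mutant over wild type, for regions assigned to named vascular, blood and cardiac genes, labelled by gene, chromosome and GRCz10 start, with 1 library per genotype. Bars are 95% counting intervals, circles are regions within 1 kb of the TSS and squares are regions further away; all 3 etv2 regions lie below 0, and the upstream lmo2 region at −1.61 and the znfl2a region at −1.91 lie furthest from it.

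As a group, regions assigned to endothelial genes were lower in the mutant library than random lists of the same level, through part of their members. Of 33 regions at 20 genes, 13 were lower and 6 higher beyond their counting intervals. The median log2 ratio was −0.17 (−0.43 to 0.10), at the 0.06 percentile of 10000 random lists matched on level. The interval of this median included 0. Paraxial and epidermal lists also lay under the 2.5 percentile of such random lists. A low percentile was therefore not particular to endothelial genes, and whether they differ from a wider lowering of developmental genes was not tested. Besides kdrl, tek and etv2, the lower regions included 1 each at the apelin receptor gene aplnrb (−0.82, −1.25 to −0.42) and the neuropilin gene nrp1b (−0.81, −1.41 to −0.21). Another region of each gene was higher, at 0.45 (0.09 to 0.80) for aplnrb and 0.63 (0.01 to 1.32) for nrp1b. The remaining lower regions, named after their values were seen, were at dll4, mef2cb, nrp1a, hhex and fli1b, and the other higher ones at cldn5b, yrk, pecam1 and fli1a. The 17 regions of this list within 1 kb of a TSS had a median of 0.02, although the kdrl and etv2 promoters were among the low ones. With regions up to 50 kb away added, the 60 regions had a median of −0.30, which 0 percent of random lists went below.

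Regions of blood genes had a median close to that of the endothelial list but stood apart less clearly. Among 21 regions at 16 genes of the hematopoietic and erythroid list, 15 lay below 0, 7 were lower and 1 was higher beyond the counting interval. Their median was −0.17 (−0.52 to 0.05), at the 0.945 percentile of lists matched on level. Matched on promoter class as well as level, the list lay at the 3.24 percentile. With that same match and 1 region per gene, the median was −0.08, at the 10.8 percentile, lmo2 and gata2a having had 3 regions each. With regions up to 50 kb away added, the median of 42 regions was −0.17, at the 5.98 percentile. The 5 measured genes known as targets of Npas4l, namely etv2, lmo2, tal1, gata2a and tspan18b, had 11 regions, of which 10 lay below 0, with a median of −0.29 (−0.81 to −0.13) at the 0.15 percentile. Matched on promoter class as well, they lay at the 1.13 percentile, and at the 2.84 percentile with that same match and 1 region per gene. This list is not independent of these samples. The myeloid list had 3 regions, with a median of 0.25. The promoter of irf8, a macrophage factor, had 0.60 (−0.02 to 1.29), the region at lcp1, a leukocyte actin-binding protein gene, 0.25 (0.01 to 0.50), and the promoter of cebpb −0.43 (−0.85 to −0.02).

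The lowest median of all 15 lists lay outside the blood and vascular lineages, at paraxial mesoderm and somite genes. Of 39 regions at 19 genes, 29 lay below 0, with 18 lower and 2 higher beyond their counting intervals. The median log2 ratio was −0.32 (−0.44 to −0.08), and 0 percent of 10000 random lists matched on level had a median as low. Regions at ripply2 (−1.06, −1.61 to −0.57), a repressor that acts at forming somite boundaries, and mespaa (−0.87, −1.64 to −0.24), a segmentation bHLH gene, were among the lowest. All 3 regions assigned to each of dlc, ripply1 and foxc1a, genes singled out after their values were seen, lay below 0. The promoter of mespab (0.91, 0.17 to 1.67) and a region inside tbx6 (1.96, 0.91 to 3.26), held by 34 reads against 8 after normalisation, went the other way. Another tbx6 region was lower, at −0.82 (−1.57 to −0.16).

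Cardiac and pronephric mesoderm genes did not stand apart as groups. The cardiac list, 20 regions at 12 genes, had a median of −0.06 (−0.40 to 0.13) at the 9.65 percentile, with 4 regions lower and 3 higher beyond their counting intervals. Its regions with the largest differences lay at tbx20 (−0.96, −1.90 to −0.12), hand2, gata6 (0.53, 0.22 to 0.85) and ltbp3 (−0.50, −1.31 to 0.19). Another tbx20 region had 0.30 (0.01 to 0.59) and another ltbp3 region 0.20 (−0.63 to 0.99). Further gata6 regions had −0.08 (−0.39 to 0.22) and −0.37 (−0.84 to 0.05). The pronephric list, 14 regions, had a median of 0.06 (−0.26 to 0.34) at the 40.6 percentile. Promoters of lhx1a (−0.54, −0.95 to −0.16) and osr1 (−0.47, −0.80 to −0.14) were lower in the mutant library, and those of sim1a (0.45, 0.10 to 0.82) and pax8 (0.35, 0.02 to 0.68) higher. The pronephric median was −0.02 under scaling by the highest 10% of regions, and −0.18 at the 7.82 percentile with regions up to 50 kb away added, of which 18 of 22 lay below 0.

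Axial, neural and neural crest genes likewise had medians near 0. The notochord and prechordal plate list, 16 regions, had a median of 0.09 (−0.29 to 0.30) at the 52.0 percentile, with higher values at gsc (0.67, 0.39 to 0.94), chd (0.61, 0.31 to 0.92) and foxa2 (0.81, 0.23 to 1.47), and −0.49 (−1.12 to 0.07) at noto. In the neural list, 22 of 43 regions lay below 0, with a median of −0.01 (−0.12 to 0.10) at the 5.58 percentile. The promoters of the forebrain gene otx2 (0.83, 0.53 to 1.142) and of zic1 (0.53, 0.32 to 0.74) were higher in the mutant library, while a region inside pax6b (−0.69, −0.91 to −0.48) and the promoter of sox1b (−0.68, −1.10 to −0.28) were lower. The neural crest and placode list, 21 regions, had a median of 0.09 (−0.07 to 0.22) at the 53.1 percentile. Its examples were tfap2a (−0.92, −1.52 to −0.38), snai1b (−0.43, −0.73 to −0.13), sox10 (0.44, 0.06 to 0.82) and six1b (0.68, −0.01 to 1.40).

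Epidermal genes lay low, with 10 of 13 regions below 0, 6 lower and 3 higher beyond their counting intervals, and a median of −0.20 (−0.75 to 0.27) at the 1.04 percentile. With regions up to 50 kb away added, the list moved to a median of −0.18 over 31 regions at the 6.95 percentile. The keratin promoter krt5 (−0.75, −1.16 to −0.38) and the promoter of the epidermal factor grhl1 (−1.19, −2.37 to −0.29) were lower in the mutant library. Both regions of klf2b, named after their values were seen, were higher (0.40, 0.06 to 0.73, and 0.27, 0.08 to 0.47). Within cldni, a claudin gene, one region held 50 against 117 normalised reads (−1.21, −1.75 to −0.73) and another 283 against 23 (3.56, 3.05 to 4.32). The endoderm list, 18 regions, had a median of −0.04 (−0.18 to 0.14) at the 15.8 percentile, with 1 region lower and 2 higher beyond their counting intervals. The lower one lay at foxa1 (−1.20, −1.92 to −0.60) and the higher ones at foxa2 (0.81, 0.23 to 1.47) and gata6 (0.53, 0.22 to 0.85). Other foxa1 regions had 0.38 (−0.05 to 0.83) and 0.01 (−0.27 to 0.30), and a sox32 region had −0.43 (−1.18 to 0.25). The hatching gland list comprised 3 promoter regions with a median of 0.23, at klf17 (0.25, −0.11 to 0.61), xbp1 (0.23, 0.06 to 0.40) and cd63 (0.18, −0.17 to 0.53), at the 77.0 percentile. One region stood for the yolk syncytial layer list, at ttr, with 40 against 14 normalised reads (1.45, 0.63 to 2.49).

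Broadly expressed control genes did not stand apart from random lists. Of their 18 regions 14 lay above 0, 8 were higher and 0 lower beyond their counting intervals, with a median of 0.21 (0.03 to 0.33) at the 94.6 percentile. The median was 0.07 at the 69.8 percentile with regions up to 50 kb away added, 0.11 (−0.05 to 0.32) after centring by level and promoter class, and 0.26 at the 97.1 percentile with 1 region per gene. Regions of lsm12b (0.60, 0.45 to 0.76, and 0.80, 0.39 to 1.24) and the promoter of ubc (0.55, 0.30 to 0.80) were higher, and the sdha promoter had −0.45 (−1.08 to 0.16). Of the 14 lists other than the known targets, 4 had a median under the 2.5 percentile (endothelial, hematopoietic and erythroid, paraxial mesoderm and somite, epidermis) and none lay among the highest 2.5 percent. Low percentiles thus occurred in several lineages and on the low side only, so they do not by themselves mark out the endothelial or blood lists. When random lists were matched on promoter class as well as level, the hematopoietic and erythroid list moved to the 3.24 percentile, and the endothelial, paraxial and epidermal lists were at 0.2, 0 and 0.84. With regions up to 50 kb away added, 2 of the 14 lists, endothelial and paraxial, stayed under the 2.5 percentile.

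**Figure D2:**
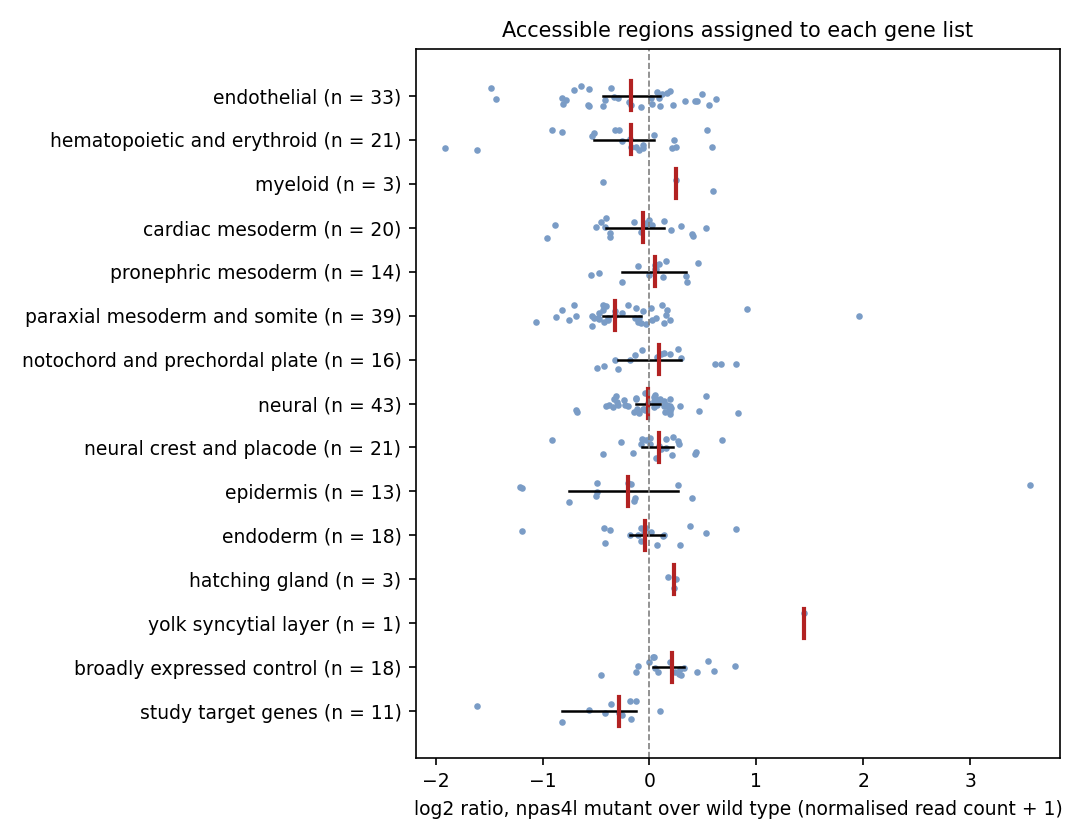
Log2 ratio of the normalised read count + 1, npas4l mutant over wild type, for each region assigned to a gene of 15 lists, with 1 library per genotype. Points are regions, red bars are list medians and black lines are 95% intervals of the median, drawn for lists of at least 6 regions; the paraxial mesoderm and somite median lies at −0.32 and the broadly expressed control median at 0.21.

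Across all regions, 1445 were at least 2-fold lower and 1357 at least 2-fold higher in the mutant library. The balance depended on the setting: 1038 were lower and 1666 higher with the level trend removed, and 954 and 1632 with the level and promoter class trend removed. Redrawing the reads of each region with no difference between libraries gave a mean of 37.98 lower and 29.7 higher over 100 draws, and at most 52 and 45. The interquartile range of the log2 ratio was 0.614, against 0.255 from counting error alone, so counting intervals understate the spread between these 2 libraries. Regions with a mean of 20 to 50 normalised reads passed the 2-fold rule in 19.1% of cases, and regions above 500 in 0.964%. None of the libraries had a replicate to show how much of this spread separates any 2 embryos.

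The largest differences did not lie at blood or vascular genes. Among assigned genes, the highest ratio lay at slc6a16a, a transporter gene of the SLC6 family. Its region 1579 bp from the TSS held 942 normalised reads in the mutant library and 0 in the wild type. With a floor of 3 reads in place of 0 it was 334-fold higher, and the lower 95% limit of its log2 ratio was 8.08. Regions at sptssb (250 against 0, 88.8-fold with that floor, lower limit 6.16) and at a gene with a clone-style name on chromosome 4 (79 against 0, 28.0-fold, lower limit 4.47) followed. The name pattern used to leave out clone names did not cover this last one. The others of the 12 highest were ggctb, 5S_rRNA, cep126, ftr09, adgrf3b, cldni, galnt7, nlrc3l and ccdc127a, with log2 ratios from 3.17 at ccdc127a to 5.11 at ggctb (3.65 to 11.5). At the other end, a region at abhd18 held 0 normalised reads in the mutant and 166 in the wild type library. It was 52.0-fold lower with that floor, and the upper 95% limit of its log2 ratio was −5.39. The region at DHX37 had −5.14 (−8.69 to −3.74), that at znf1177 −4.91 (−11.1 to −3.26) and that at cirbpa, a cold-inducible RNA-binding protein gene, −4.70 (−5.80 to −4.01). The remaining 8 lowest were sptlc1, PKIG, cyp2x7, clk2a, METTL22, lamtor1, p2ry6 and tcp1, the last with −3.89 (−6.01 to −2.69). Of these, 5S_rRNA, ftr09, nlrc3l and znf1177 belong to multigene families whose copies can share reads, so their values are uncertain. Many of the named regions, among them slc6a16a, sptssb, ggctb, abhd18 and DHX37, held at most 3 recovered reads in 1 library. Such regions may come from sequence differences between the embryos, as the closing observations set out, so they need not reflect accessibility. Of the 24 regions, 2 of the highest and 3 of the lowest 12 lay within 1 kb of a TSS.

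Promoter regions had higher log2 ratios than other regions. Regions within 1 kb of a TSS had a median log2 ratio of 0.11 (0.10 to 0.12), assigned regions further away 0 (−0.02 to 0.00), and regions without an assigned gene −0.12 (−0.13 to −0.11). At least 2-fold lower values were found in 1.02% of promoter regions and 6.2% of regions without an assigned gene, and at least 2-fold higher values in 2.68% and 4.35%. Promoter regions held 54.0% of the nuclear normalised reads of the mutant library and 52.5% of those of the wild type. The promoter median was positive under each scaling tried, and 0.03 under scaling by the highest 10% of regions.

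**Figure D3:**
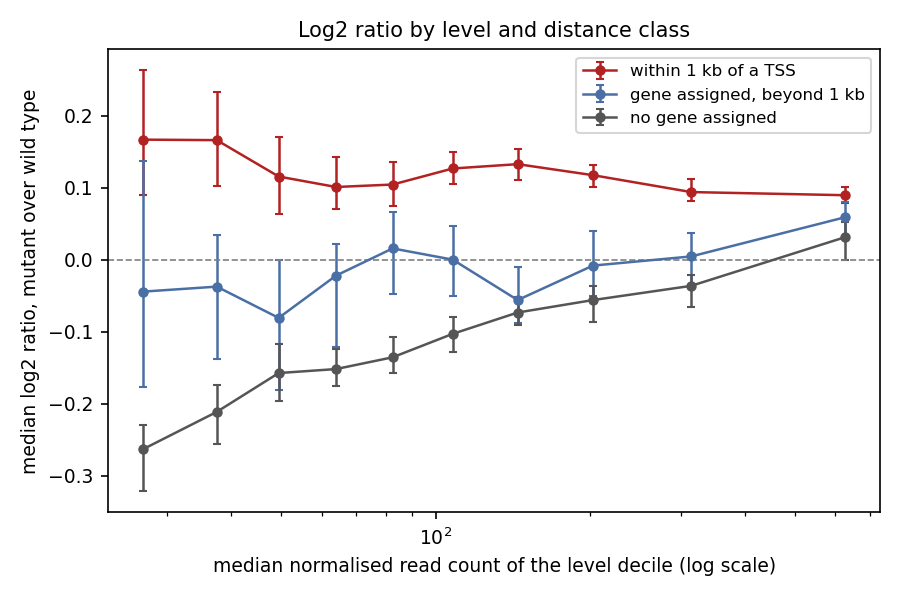
Median log2 ratio of the normalised read count + 1, npas4l mutant over wild type, against the median normalised read count (log scale) of each level decile, with 1 library per genotype. Lines are regions within 1 kb of a TSS, assigned regions further away and regions without an assigned gene, and bars are 95% intervals of the median over regions; in the lowest decile the medians are 0.17, −0.04 and −0.26, and in the highest 0.09, 0.06 and 0.03.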

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

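Matching on promoter class, 1 region per gene, nearest-TSS assignment and leaving out near-absent regions were chosen after the results were seen. Counts of lower and higher regions were 4472 and 4074 at 1.5-fold, and 472 and 586 among regions with a mean of at least 50, which tests fewer and deeper regions. With the level trend removed 1038 were lower and 1666 higher, with the level and promoter class trend removed 954 and 1632, and under highest-tenth scaling 1697 and 1102, and 1072 and 1079 with a pseudocount of 5, so which direction held more regions depended on the setting. The median of all regions was −0.0289 under total scaling, −0.0026 under TMM scaling, −0.0736 under highest-tenth scaling and 0.0194 with a mean of at least 50; no scaling shifted log2 ratios by over 0.1. The interquartile range was 0.515 with a mean of at least 50, 0.587 with a pseudocount of 5, 0.598 with the level trend removed and 0.574 with the class trend also removed. The promoter median was 0.0791 under total scaling, 0.0339 under highest-tenth scaling, 0.0852 with the level trend removed and 0 with the class trend removed, by construction. The neural crest median was −0.0743 with regions up to 50 kb away, and the hatching gland median was 0.155 under highest-tenth scaling and 0.119 with the class trend removed; the cause was not tested. List medians near 0 also crossed it within their intervals: endothelial 0.0159 for promoters alone, myeloid −0.0907 with a mean of at least 50, pronephric −0.0170 under highest-tenth scaling and −0.182 with regions up to 50 kb away, and notochord and neural under some settings. Of 244 values of 20 main results, 57 equalled the main value, among them those of settings that removed no region; of the 187 that differed, 167 stayed within the main interval or, for counts, within 1.5 times; of 430 values of 86 named regions, 425 stayed within the counting interval and the 5 others came with a pseudocount of 5, with 0 reversed. The level minimum removed 0 regions, so dropping it says nothing. No named region could move far under these scalings, so its staying within the counting interval was largely set beforehand and says little. No paired analysis was possible because there was 1 library per genotype, so leaving out a library could not be run either; the motif comparison and the nearest TSS within 10 kb were not run. Each of the 1445 lower and 1357 higher regions had a counting interval that excluded a ratio of 1; the spread between embryos of 1 genotype is not known.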

Other observations

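All tests in this part were chosen after the data were examined; the tests of level, wild type background and posterior cells had bounds set before their values were seen, the others after. Gene families were also looked at, some of which share regions with the lists of the report. Hox genes, which pattern the body axis, were low in the mutant library, and of these hoxb1a and hoxb1b were also in the neural list. Of 82 regions at 46 hox genes, 63 lay below 0 and the median log2 ratio was −0.29 (−0.40 to −0.19), with 42 regions lower and 6 higher beyond their counting intervals. The median was below 0 in each of the hox clusters on 7 chromosomes, from −0.41 at hoxc on chromosome 23 to −0.11 at hoxd on chromosome 9. Intervals of a median and random lists take regions as independent. Where neighbouring regions shift together, as they may in a cluster, both overstate how far a family stands apart. The hoxb4a promoter on chromosome 3 held 125 against 263 normalised reads, a log2 ratio of −1.07 (−1.40 to −0.76), and the hoxa9a promoter on chromosome 19 held 37 against 88 (−1.23, −1.85 to −0.67). Among Hairy-related repressors of the her, hes and hey families, 32 of 44 regions lay below 0, with a median of −0.17 (−0.26 to −0.10) and −0.55 (−0.69 to −0.41) at the her9 promoter. Notch receptors and ligands had a median of −0.14 (−0.35 to 0.02) over 26 regions, with 9 lower and 0 higher beyond counting error, among them notch2 (−1.17, −1.83 to −0.59), dlc (−0.69, −0.94 to −0.45) and the endothelial ligand gene dll4 (−0.78, −1.40 to −0.18). The dlc region was also in the paraxial list and the dll4 region in the endothelial list.

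In all, 19 gene families were looked at. Some share regions with the lists of the report, so their percentiles are not independent of those. Keratins share krt4, krt5, krt8 and krt18 with the epidermis list, and her genes share her1 and her7 with the paraxial list. Notch genes share dlc and dld with the paraxial list and dll4 and notch1b with the endothelial list. The cardiac list holds fgf8a and the paraxial list foxc1a. Against random lists matched on level and promoter class, 6 of the 19 families had a median under the 2.5 percentile, namely hox (0), her, hes and hey (0.09), keratins (0.17), fgf (0.28), Notch (0.46) and fox genes (1.72). Of these 6, the interval of the median, not centred, included 0 for Notch, for keratins (−0.49, −0.75 to 0.72), fgf (−0.24, −0.45 to 0.21) and fox genes (−0.04, −0.15 to 0.01). Centred by level and promoter class, it still included 0 for keratins and fgf genes. It then lay below 0 for Notch (−0.20, −0.38 to −0.06) and fox genes (−0.12, −0.21 to −0.05). Proteasome subunits, with a median of 0.22 (0.13 to 0.31), lay at the 95.9 percentile, kelch-like genes at 93.9 and ribosomal protein genes at 75.2. The other 10 families (znf, sox, tbx, wnt, collagen, protocadherin, heat shock and cytochrome P450 genes, cell cycle genes and NADH dehydrogenase subunits) lay between the 13.9 and 89.7 percentiles. Centred by level and promoter class, the proteasome median was 0.10 (−0.003 to 0.21). Before the pseudocount, the scalings tried shifted every log2 ratio alike, by between −0.0749 and −0.0026. With the pseudocount, regions with few reads in a library shifted less.

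The long arm of chromosome 4, a repeat-rich and late-replicating part of the zebrafish genome, was higher in the mutant library. Its 460 regions beyond 27 Mb had a median log2 ratio of 0.34 (0.27 to 0.40), with 67 at least 2-fold higher and 9 at least 2-fold lower. Repeated copies can share reads, so the values of this arm are uncertain, and the interval takes neighbouring regions as independent. The 819 regions up to 27 Mb had a median of −0.02 (−0.06 to 0.02). All 7 bins of 5 Mb beyond 30 Mb that held at least 30 regions were among the 10 highest of 275 such bins of the genome, as was chromosome 22 from 5 to 10 Mb (0.46 over 128 regions). The lowest bins were chromosome 9 from 10 to 15 Mb (−0.34 over 117 regions) and chromosome 23 from 20 to 25 Mb (−0.30 over 195 regions). The latter held the her9 promoter and the lowest regions of her4.1 and her4.4. Promoters on this arm had a median of 0.39 over 182 regions and regions without an assigned gene 0.31 over 218. The 6 mitochondrial regions held 13.4% of normalised reads in the wild type and 11.6% in the mutant library.

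In 114 regions one library held at most 3 recovered reads, while the lowest mean of any region was 20.5. They lay on 22 chromosomes, 80 of them (70.2%) without an assigned gene, against 51.2% of all regions. In the gene lists 0 of them fell, which says little because the lists hold 254 of the 35854 regions. Counting error is argued against, since random draws gave a mean of 0 such regions. Loss of accessibility without Npas4l is argued against as the main source, since 36.8% (28.0 to 46.4) of them were absent in the mutant and 63.2% in the wild type library. Sequence differences between the embryos, such as deletions or insertions against the reference, may be the source, which these tables cannot decide because either embryo could lack a sequence.

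Promoter regions were higher than other regions in the mutant library by 0.20 (0.19 to 0.21) on the log2 scale. The level of the regions is argued against as the whole cause, since the difference within level deciles was 0.223 (0.208 to 0.238). More background reads in the wild type library could add to low regions without a promoter, and the difference did narrow to 0.0894 (0.0736 to 0.105) in the highest 20% of regions, between the bounds set for and against this explanation. In the lowest level decile, promoters had 0.17 (0.09 to 0.26) and regions without an assigned gene −0.26 (−0.32 to −0.23), at the same median level. Background spread evenly would shift regions of equal level and width alike. Promoters were the wider class, with a median of 505 against 335 bp over all levels. By these widths evenly spread background would not account for the difference, but widths within deciles were not compared. Whether background contributed is therefore not decided. The genotype, the embryo and the library preparation cannot be told apart with 1 library each.

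Low values at hox and somite genes covered 92 of 121 regions in both groups together. The promoter and distal composition of these groups is argued against as the whole cause, since 0 percent of random lists matched on level and promoter class were as low as either. Centred by level and promoter class, the medians were −0.37 (−0.41 to −0.25) for hox and −0.30 (−0.50 to −0.09) for somite genes. Both measures take regions as independent, and the hox group was chosen after the data were seen. Fewer posterior cells in the mutant embryo may be a source, but hox groups 9 to 13 minus groups 1 to 4 gave −0.0389 (−0.43 to 0.23), an interval too wide to decide; the middle groups 5 to 8 had the lowest median (−0.33, −0.42 to −0.26, 22 of 23 regions below 0). Developmental patterning genes could be lower in general, and the neural list, centred by level and promoter class, had a median of −0.0473 (−0.16 to 0.08), which leaves this open. Other patterning groups went both ways against lists matched on level and promoter class. Notochord, neural crest and wnt genes lay at the 60.7, 67.0 and 55.7 percentiles, and fgf and fox genes at 0.28 and 1.72. Genes of the her, hes and hey families and Notch genes, which share regions with the paraxial list, lay at 0.09 and 0.46. The cardiac, neural and pronephric lists lay at 9.1, 15.9 and 43.3, and tbx and sox genes at 21.3 and 29.4. A lowering was thus not shared by all such groups, but a lowering of many of them stays open. A small difference in stage between the embryos and an effect of the genotype also stay open and were not tested.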
